A study of Bos grunniens with 18 samples.

How the data were processed

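Testis tissue from 9 male yaks was analysed, 3 castrated at each of 3 ages (6 months, 18 months and 4 years). Per the labels, the tissue was washed, frozen in liquid nitrogen and extracted with Trizol, ribosomal RNA was removed with Ribo-Zero Gold, and NEBNext Ultra libraries were sequenced paired-end on an Illumina HiSeq2500. The preparation of the small RNA libraries is not given separately in the sources used here. Samples were grouped by their titles, which give the ages also stated in the treatment description. A label that differs, given under Results, was not used.

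The submitters' processing notes list fastp 0.18.0, HISAT2 2.1.0, StringTie 1.3.4 and genome build UMD3.1, without saying what each was used for. The programs that counted genes, found circRNAs and miRNAs and compared the ages are not given in the sources used here. The deposited gene table holds, per the file headers, a count per library for 22183 genes, of which 21650 carry Ensembl cattle identifiers and 533 are StringTie loci named MSTRG. These are estimated counts as deposited by the authors, since 3137 genes have a value that is not whole, and they were rounded here. Of the genes, 924 have no symbol and 1423 symbols stand on more than 1 identifier, so a shared symbol leaves the identity uncertain. The deposited circRNA table gives, per the file headers, the count of back-splice reads for 73679 circRNAs, of which 6967 have no source gene. Its coordinates on chromosome 1 reach 158496087, and whether they follow the listed build was not settled, so coordinates are as the files give them. The deposited miRNA table gives, per the file headers, a count and a TPM value for 1536 miRNAs, in a known (717), an existing (558) and another class (261). The TPM values the authors deposited equal each count divided by a library total, of which the listed miRNAs make up 82.0% to 88.0%, with 0.01 in place of 0. They were not used for tests. There are 33 miRNA sequences that stand under more than 1 name and were kept as separate entries.

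The authors also deposited a table of differing features for each pair of ages and each kind of RNA. Those hold the authors' group means in FPKM for genes, in RPM for circRNAs and in TPM for miRNAs, with a small floor where a mean would be 0. The log2 ratios in these tables are, per the file headers and as checked against the means, of 1 deposited group mean over the other. Every gene listed has a deposited FDR under 0.05, whereas the circRNA tables were selected on the p value that the authors left unadjusted, and so were the miRNA tables, of which the 6-month against 18-month table has no FDR. These tables were only compared with the calls made here. A yak reference annotation supplied beside the files was not used here, because its genes carry other identifiers.

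Library totals are given under Results. Each kind of RNA was fitted in edgeR 4.0.16 (R 4.3.3) as 1 model of its 9 libraries with age as the only factor, which leaves 6 residual degrees of freedom. Low counts were filtered with filterByExpr, libraries were scaled with TMM, and glmQLFit and glmQLFTest gave quasi-likelihood F-tests of 18 months against 6 months, 4 years against 6 months and 4 years against 18 months. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within a comparison and kind of RNA. The SE of a log2 fold change is its size divided by the square root of F. The 24 gene lists and 14 miRNA lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a correlation between members preset at 0.01. The adjustment there ran over all lists of a kind and the 3 comparisons. Gene lists needed 5 measured members and miRNA lists 3, so 13 miRNA lists were tested. The same test with the correlation estimated for each list served as an alternative. A member count adjusted over the list alone uses only the p values of its members. The direction camera tested can differ from the sign of the median, and both are then given. Single values per library were compared by exact permutation tests over the 280 groupings of 9 libraries into 3 ages. A group with no counts was set to a floor of 3 counts over the group, and the ratio is then given as a bound. With 1 to 3 counts the ratio is given with its 95% counting interval.

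The lists, comparisons, tests, alternatives and the rule for named features were fixed before the data were examined, except where the text says otherwise. The rule takes 23 anchor genes in every comparison, of which CD68 and H19 were not measured well enough to test. It also takes, per comparison and kind of RNA, the 5 features with the smallest p in each direction among those called with at least a 2-fold change and no overlap between replicates. Finally it takes up to 4 members of each gene list and up to 3 of each miRNA list with the smallest p. The text prints every tested anchor, and for length prints part of the others, a choice made after their values were seen. Some counts of miRNAs are given as a percentage of those tested or of the 1536 deposited. Chromosomes of genes were taken from the source genes of the circRNA table.

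Alternatives were DESeq2 1.42.0 with its own size factors, library size alone, upper-quartile factors and no filter beyond a count above 0. A second filter needed, in 3 libraries, a CPM of at least 1 or for circRNAs a count of at least 5. It kept fewer genes than filterByExpr and more miRNAs and circRNAs. Others were replicate number as a block, the 6 libraries of 2 ages alone, an added 2-fold threshold and leaving out each library in turn. Replicate numbers pair no animals, since each animal has 1 age. With 2 libraries left at an age, the spread is pooled over the 3 ages. The pipeline was tested on simulated data with 200 features changed at the depth and spread of these libraries. For 2-fold changes it recovered 6%, 4% and 4% of genes in the 3 comparisons, 52%, 36% and 52% of miRNAs and 0%, 0% and 0% of circRNAs. For 4-fold changes it recovered 64%, 72% and 54% of genes, 86%, 82% and 90% of miRNAs, and 2%, 6% and 2% of circRNAs. For 16-fold changes it recovered 98%, 88% and 88% of genes and 48%, 42% and 42% of circRNAs. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.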

Results

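Testis tissue came from 9 male yaks of 1 cooperative, castrated at 6 months (Y6M), 18 months (Y18M) or 4 years (Y4Y), with 3 animals per age. Each animal gave 1 ribosomal RNA-depleted library, used for gene and circular RNA (circRNA) values, and 1 small RNA library, used for microRNA (miRNA) values, making 18 libraries. Replicate numbers name different animals at each age. The sample titles and the treatment description give the ages above, whereas a separate label calls Y4Y infancy, Y6M adolescence and Y18M adulthood. Samples were grouped by title. Gene libraries held 22.95 to 33.12 M estimated counts over 22183 genes. The circRNA table held 119.8 to 227.2 k reads per library over 73679 circRNAs. The miRNA table held 4.25 to 9.68 M counts over 1536 miRNAs, with the lowest total in Y18M replicate 1. Values below are counts per 1 M counts of tested features after TMM scaling (CPM) ± SD and log2 fold changes ± SE, with n = 3 per age throughout, and adjusted p values are from edgeR. A circRNA CPM is thus relative to circRNAs alone. Intervals and floors cover counting error only.

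The first question was how the libraries of the 3 ages lay relative to one another. On a scale where the 6-month mean was 0 and the 4-year mean was 1, Y18M replicates 1, 2 and 3 lay at 0.99, 0.53 and 0.81 for genes. They lay at 0.95, 0.53 and 0.75 for miRNAs and at 0.84, 0.36 and 0.63 for circRNAs. The 18-month gene mean was 0.78 ± 0.23, against an SD of 0.03 at 6 months and 0.01 at 4 years. This scale is set by the 6-month and 4-year means, so these ages lie apart on it by construction and no test was made. The first principal component held 88.4% of the variance for genes, 79.6% for miRNAs and 48.1% for circRNAs.

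**Figure D1:**
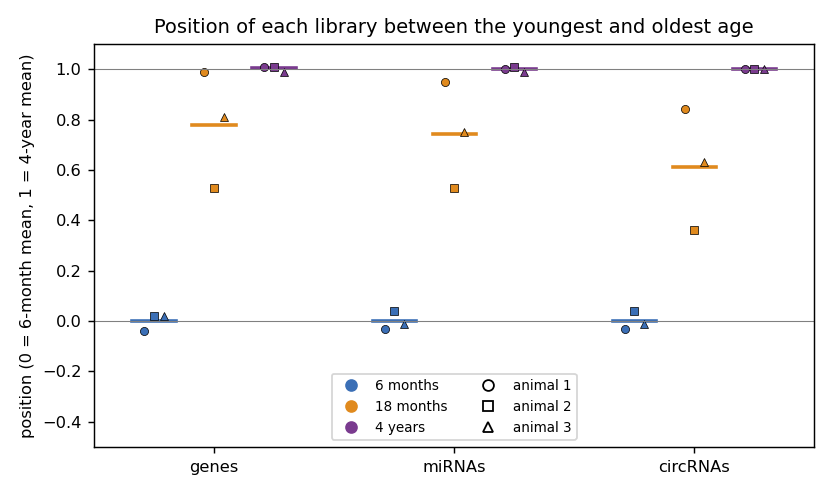
Position of each library between the 6-month mean (0) and the 4-year mean (1) on the y axis for genes, miRNAs and circRNAs. Colours give the age, marker shapes the animal and bars the age mean, and the 18-month gene libraries lie at 0.99, 0.53 and 0.81.

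The comparison of 18 months with 6 months asked which testis transcripts differed between these ages. Transcripts of meiotic and haploid germ cells were higher at 18 months, though no list passed with an estimated correlation. PRM1 (ENSBTAG00000021493), a protamine that packs sperm DNA, rose by 8.74 ± 1.16, from 0.305 ± 0.0656 to 132.3 ± 141.3 CPM (adjusted p = 0.000364). Its neighbour in chromatin condensation, the transition protein TNP1 (ENSBTAG00000019003), rose by 9.5 ± 1.35 (0.00048). AMH (ENSBTAG00000014955), the Sertoli cell hormone that regresses the Müllerian duct, fell from 884.1 ± 137.1 to 52.0 ± 45.2 CPM (log2 -4.09 ± 0.68, adjusted p = 0.00101). The matrix proteoglycan DCN (ENSBTAG00000003505) fell from 1037.9 ± 191.5 to 64.4 ± 25.2 CPM (-4.01 ± 0.35, 6.83e-05). Below, values in parentheses after a gene are its identifier where first named, its log2 fold change ± SE and its adjusted p.

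Of the 35 measured genes of the acrosome and round spermatid list, 34 rose and 1 did not pass the test (median log2 fold change 8.27, adjusted p = 1.98e-11, and adjusted p = 0.503 with an estimated correlation). Among them, ACRV1 (ENSBTAG00000033384), an acrosomal vesicle protein, rose to 85.0 ± 83.5 CPM (10.1 ± 1.23, 0.000245). The acrosomal protease ACR (ENSBTAG00000010182, 9.73 ± 0.83, 6.56e-05) and SPATA16 (ENSBTAG00000031802, 8.43 ± 0.79, 8.33e-05), required for acrosome formation, rose as well. The mean log2 CPM of the list was 6.57, 3.21 and 5.48 in Y18M replicates 1, 2 and 3, against -1.33 ± 0.4 at 6 months. All but 1 of the 15 sperm chromatin condensation genes rose (median 8.74, or 7.48 with genes at 0 set to their bound, adjusted p = 1.71e-06, and adjusted p = 0.503 with an estimated correlation). They included CAMK4 (ENSBTAG00000035662, 3.48 ± 0.37, 0.000129) and the histone variant H2AB2 (ENSBTAG00000048126), at least 178.0-fold higher (0.000113). For the sperm flagellum list, 49 of 51 rose (6.29, adjusted p = 5.61e-15, and adjusted p = 0.503 with an estimated correlation), with the fibrous sheath anchor AKAP4 (ENSBTAG00000016399, 5.69 ± 0.95, 0.00106), the axonemal dynein DNAH17 (ENSBTAG00000000920, 9.11 ± 0.64, 4.61e-05) and SEPTIN12 (ENSBTAG00000016330, 9.5 ± 0.66, 4.61e-05), of the annulus. Germ cell isoenzymes, the testis forms of housekeeping enzymes, rose in 18 of 20 cases (4.82, adjusted p = 6.64e-07, and adjusted p = 0.503 with an estimated correlation). The sperm lactate dehydrogenase LDHC (ENSBTAG00000002488, 6.6 ± 0.57, 6.71e-05) and the cytochrome c oxidase subunit COX6B2 (ENSBTAG00000007200, 5.66 ± 0.47, 6.14e-05) were among them.

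Meiotic prophase genes rose in 39 of 40 cases and 1 fell (median 4.05, adjusted p = 5.32e-13, and adjusted p = 0.503 with an estimated correlation). SYCP3 (ENSBTAG00000002492), of the synaptonemal complex, reached 14.8 ± 0.771 CPM from 0.591 ± 0.31 (4.64 ± 0.38, 6.19e-05). Its partner SYCP2 (ENSBTAG00000003608, 4.99 ± 0.31, 4.31e-05), the meiotic cohesin STAG3 (ENSBTAG00000010496, 6.37 ± 0.46, 4.73e-05) and MEIOC (ENSBTAG00000039485, 7.7 ± 0.5, 4.39e-05), which maintains meiotic entry, also rose. In the piRNA pathway, which silences transposons, 22 of 25 rose and 3 did not pass (4.39, adjusted p = 2.92e-09, and adjusted p = 0.503 with an estimated correlation). These included PIWIL1 (ENSBTAG00000006468, 7.85 ± 0.56, 4.69e-05), TDRD5 (ENSBTAG00000002407, 6.61 ± 0.51, 5.18e-05) and the germ cell helicase DDX4 (ENSBTAG00000008871, 4.48 ± 0.39, 6.85e-05). Differentiating spermatogonia genes rose in 11 of 12 cases and 1 fell (2.38, adjusted p = 0.000492, and adjusted p = 0.503 with an estimated correlation). STRA8 (ENSBTAG00000001346), induced by retinoic acid before meiosis, rose by 2.12 ± 0.5 (0.00607), DMRTB1 (ENSBTAG00000009062) by 5.57 ± 0.43 (5.18e-05) and SOHLH2 (ENSBTAG00000018955) by 4.15 ± 0.38 (7.95e-05). Undifferentiated spermatogonia genes did not move together: 4 of 15 rose, 5 fell and 6 did not pass (median 0.09, mean -0.21, tested direction down, adjusted p = 0.55). NANOS3 (ENSBTAG00000000399) rose by 3.36 ± 0.36 (0.000142) and the laminin receptor ITGA6 (ENSBTAG00000017266) fell by 3.43 ± 0.22 (4.39e-05). UCHL1 (ENSBTAG00000005078), a spermatogonial ubiquitin hydrolase, did not pass (0.62 ± 0.41, 0.216), and passed without Y18M replicate 1 (0.94, 0.0406). Mitotic cell cycle genes rose in 30 of 38 cases and 1 fell (1.74, adjusted p = 8.41e-08, and adjusted p = 0.503 with an estimated correlation), with CDC20 (ENSBTAG00000009819, 4.36 ± 0.43, 9.59e-05) and the helicase MCM4 (ENSBTAG00000017021, 2.07 ± 0.21, 0.000119).

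**Figure D2:**
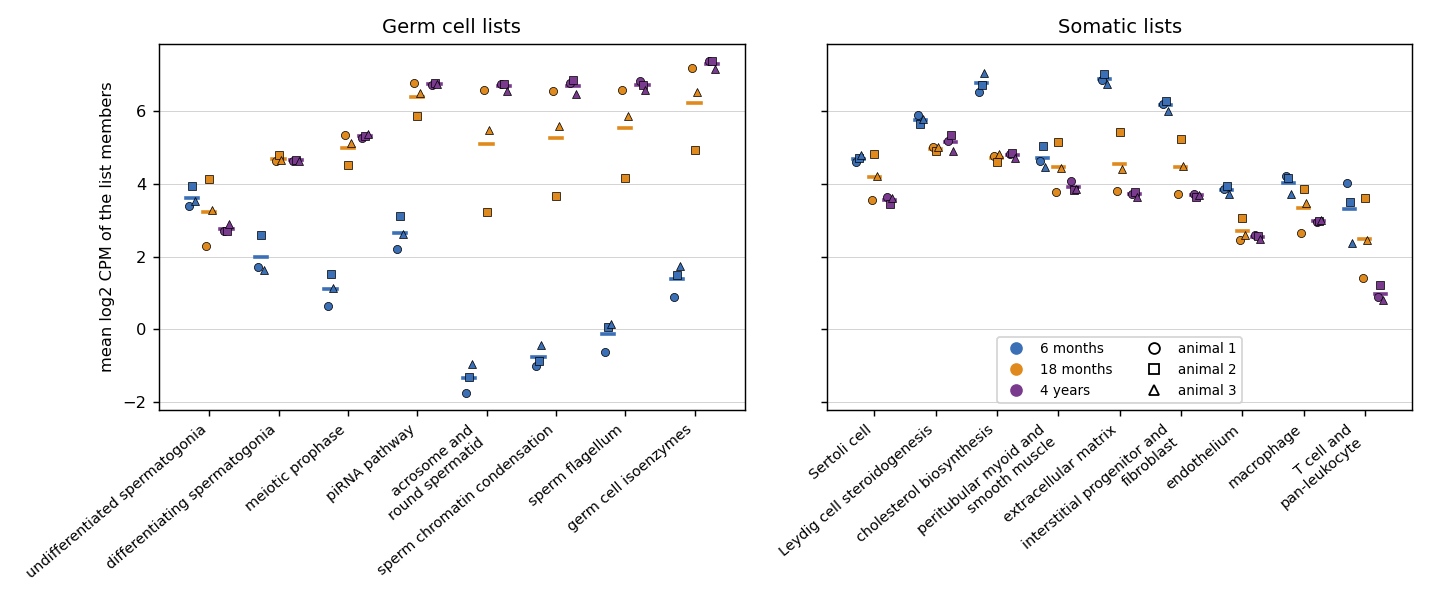
Mean log2 CPM of the members of each gene list per library on the y axis, by age, with 8 germ cell lists in 1 panel and 9 somatic lists in the other. Colours give the age, marker shapes the animal and bars the age mean, and the acrosome list lies at 6.57, 3.21 and 5.48 in the 18-month libraries.

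Sertoli cell genes fell in 14 of 30 cases, rose in 4 and did not pass in 12 (median -1.01, adjusted p = 0.0415, and adjusted p = 0.65 with an estimated correlation). That call was lost without Y18M replicate 1 (0.0626). INHA (ENSBTAG00000009972), the inhibin alpha subunit, fell from 4098.5 ± 476.4 to 366.5 ± 297.3 CPM (-3.48 ± 0.55, 0.000825). INHBA (ENSBTAG00000048508) fell (-3.41 ± 0.37, 0.00014) while FATE1 (ENSBTAG00000006820) rose (3.71 ± 0.37, 9.95e-05). SOX9 (ENSBTAG00000045824), the Sertoli cell transcription factor, fell by 0.77 ± 0.26 (0.03). This SOX9 call was lost without any 1 of the Y6M replicates 1, 2 and 3 (0.0662, 0.0699 and 0.0688), without Y18M replicate 1 (0.0545) or 3 (0.0853), and with library size alone (-0.35, 0.33). Among 22 blood-testis barrier junction genes, 6 rose, 10 fell and 6 did not pass (median -0.51, mean 0.1, tested direction down, adjusted p = 0.326). CLDN11 (ENSBTAG00000019060), the tight junction protein of that barrier, rose from 8.56 ± 8.21 to 288.7 ± 67.8 CPM (5.07 ± 0.65, 0.00031). ESPN (ENSBTAG00000006515), an actin bundler of Sertoli cell junctions, rose (4.93 ± 0.3, 4.18e-05) and F11R (ENSBTAG00000017846) fell (-1.92 ± 0.3, 0.000747).

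Leydig cell steroidogenesis genes fell in 12 of 20 cases and rose in 4 (median -1.28, adjusted p = 0.0173, and adjusted p = 0.503 with an estimated correlation). Among those that fell were the side-chain cleavage enzyme CYP11A1 (ENSBTAG00000006934, -4.44 ± 0.29, 4.54e-05) and HSD3B1 (ENSBTAG00000006769, -2.89 ± 0.46, 0.000868). INSL3 (ENSBTAG00000025775), a Leydig cell peptide hormone, fell from 11277.1 ± 2967.0 to 3902.0 ± 1539.2 CPM (-1.53 ± 0.4, 0.00967). STAR (ENSBTAG00000033345), which brings cholesterol into mitochondria, and CYP17A1 (ENSBTAG00000014335) carry symbols shared with another identifier, so their identity is uncertain. They fell by 4.88 ± 0.46 (8.33e-05) and 3.15 ± 0.37 (0.000212). CYP19A1 (ENSBTAG00000014890), the aromatase that makes oestrogen, rose from 0.19 ± 0.0332 to 58.0 ± 34.6 CPM (8.22 ± 0.57, 4.61e-05). Cholesterol biosynthesis genes fell in 18 of 24 cases and none rose (-2.23, adjusted p = 4.22e-07, and adjusted p = 0.503 with an estimated correlation), including MSMO1 (ENSBTAG00000003068, -3.26 ± 0.23, 4.61e-05) and DHCR7 (ENSBTAG00000016465, -2.93 ± 0.24, 6.23e-05).

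Extracellular matrix genes fell in 29 of 36 cases and 1 rose, or 30 and 2 adjusted over the list alone (median -2.09, adjusted p = 3.49e-08, and adjusted p = 0.503 with an estimated correlation). The fibrillar collagen gene COL1A1 (ENSBTAG00000013103, -2.64 ± 0.66, 0.00796) and the proteoglycan LUM (ENSBTAG00000001745, -6.47 ± 0.61, 8.55e-05) fell with DCN. The list's mean log2 CPM was 3.79, 5.41 and 4.4 in Y18M replicates 1, 2 and 3, against 6.85 ± 0.13 at 6 months. Interstitial progenitor and fibroblast genes fell in 15 of 23 cases, or 16 adjusted over the list alone, and none rose (-1.52, adjusted p = 5.39e-05, and adjusted p = 0.503 with an estimated correlation). TCF21 (ENSBTAG00000021827, -3.37 ± 0.44, 0.000334) and IGFBP3 (ENSBTAG00000003994, -3.12 ± 0.32, 0.000113) were examples. Peritubular myoid and smooth muscle genes went both ways, with 5 of 17 rising and 7 falling (-0.63, adjusted p = 0.403). ACTA2 (ENSBTAG00000014614), smooth muscle actin, rose by 2.13 ± 0.57 (0.0111) and the myosin MYH11 (ENSBTAG00000015988) by 2.39 ± 0.49 (0.00292), and CALD1 (ENSBTAG00000013953) fell by 1.97 ± 0.35 (0.00143). Endothelium genes fell in 14 of 23 cases and 1 rose (-1.4, adjusted p = 0.000853, and adjusted p = 0.503 with an estimated correlation). PECAM1 (ENSBTAG00000012066, -1.4 ± 0.26, 0.00189) and KDR (ENSBTAG00000000782, -1.62 ± 0.17, 0.000121) fell, whereas VWF (ENSBTAG00000012265, 2.79 ± 0.34, 0.000246) rose.

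Macrophage genes rose in 3 of 21 cases and fell in 5, or 3 and 3 adjusted over the list alone (median -0.76, adjusted p = 0.0599). CD14 (ENSBTAG00000015032) rose by 3.79 ± 0.5 (0.000341) and ITGAM (ENSBTAG00000047238) fell by 3.25 ± 0.45 (0.000444). None of 22 T cell and pan-leukocyte genes passed (-0.75, adjusted p = 0.0825). CD3G (ENSBTAG00000006453) had -1.29 ± 0.59 (0.088), and passed without Y18M replicate 2 (-1.7, 0.0299). The macrophage list passed without Y6M replicate 3 (0.0199), Y18M replicate 2 (0.0339) or Y18M replicate 3 (0.0478), and the T cell list without Y6M replicate 3 (0.00544) or Y18M replicate 2 (0.00841). Of 7 erythrocyte genes, 2 rose, or 1 adjusted over the list alone (0.67, adjusted p = 0.724). HEMGN (ENSBTAG00000032206) had 3 counts at 6 months and was 852.9-fold higher at 18 months (counting interval 291.6 to 4137.8, adjusted p = 0.000588). Rete testis, efferent duct and epididymis genes rose in 1 of 8 cases and fell in 3 (-1.31, adjusted p = 0.269), with EPCAM (ENSBTAG00000006474) rising by 4.43 ± 0.46 (0.000123) and ESR1 (ENSBTAG00000007159) falling (-2.51 ± 0.41, 0.000901).

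Imprinted growth genes fell in 15 of 24 cases and rose in 4, or 17 and 4 adjusted over the list alone (median -1.68, adjusted p = 0.00239, and adjusted p = 0.503 with an estimated correlation). The fetal growth factor IGF2 (ENSBTAG00000013066) fell from 897.9 ± 85.1 to 267.5 ± 190.8 CPM (-1.75 ± 0.45, 0.0094). The cell cycle inhibitor CDKN1C (ENSBTAG00000031184, -4.48 ± 0.23, 2.24e-05) and SGCE (ENSBTAG00000021282, -2.18 ± 0.23, 0.000128) fell, whereas ZIM2 (ENSBTAG00000011664, 3.22 ± 0.28, 6.83e-05) rose. Hypoxia response genes rose in 7 of 29 cases and fell in 15 (-0.95, adjusted p = 0.058), and the list passed without Y6M replicate 1 (0.0448). The carbonic anhydrase CA9 (ENSBTAG00000011420) rose by 7.73 ± 0.64 (6.21e-05), and P4HA1 (ENSBTAG00000032996) fell by 2.54 ± 0.24 (8.91e-05). Oxidative phosphorylation genes rose in 6 of 35 cases and fell in 11 (-0.28, adjusted p = 0.431), among them NDUFA9 (ENSBTAG00000005465, 1.03 ± 0.19, 0.00156) and SDHD (ENSBTAG00000016266, -1.31 ± 0.17, 0.000329).

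Over all genes, the smallest p values among those that rose belonged to the beta-defensin DEFB119 (ENSBTAG00000003364, also on the Sertoli cell list), the glycine transporter SLC6A9 (ENSBTAG00000006043, 9.23 ± 0.38, 9.52e-06, identity uncertain because its symbol is shared), the serine protease PRSS45 (ENSBTAG00000031447, 8.84 ± 0.41, 2.02e-05), the CDK1 inhibitory kinase PKMYT1 (ENSBTAG00000004729, 6.17 ± 0.32, 2.24e-05) and the synaptonemal SYCE2, of the meiotic list (ENSBTAG00000016213, 6.47 ± 0.36, 3.03e-05). DEFB119 had 2 counts at 6 months and was 6505.8-fold higher at 18 months (counting interval 1800.7 to 53724.5). The chemokine CCL25 (ENSBTAG00000005581) fell from 306.8 ± 60.9 to 0.598 ± 0.2 CPM (-8.99 ± 0.35, 9.52e-06). The protease RHBDL2 (ENSBTAG00000008023, -5.18 ± 0.25, 2.24e-05), the kallikrein KLK1 (ENSBTAG00000018539, -5.69 ± 0.31, 2.93e-05) and the glypican GPC6 (ENSBTAG00000054671, -5.4 ± 0.27, 2.24e-05, symbol shared) fell too. In all, 10026 of 16742 genes tested passed an adjusted p of 0.05, 5481 of them higher and 4545 lower. The age groups did not overlap for 65.1% of genes, where chance gives 10%. With library size alone the median log2 fold change shifted by 0.4 and 72.6% of called genes were higher, against 54.7% with TMM.

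**Figure D3:**
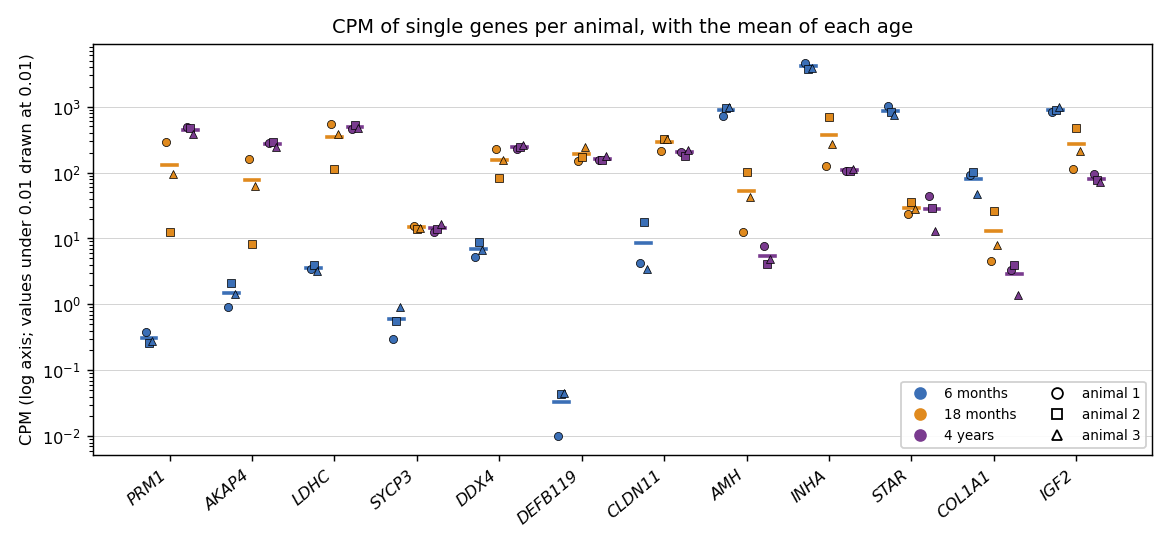
CPM of selected genes in each animal on a log axis, by age, with marker shapes for the animal and bars for the age mean. PRM1 lies at 0.305 ± 0.0656 CPM at 6 months and 132.3 ± 141.3 CPM at 18 months.

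Among miRNAs at 18 months against 6 months, members of the miR-34 and miR-449 family, which is abundant in meiotic and haploid male germ cells, had the largest list median. All 5 rose (median 6.71, adjusted p = 0.00498, and adjusted p = 0.524 with an estimated correlation). The level of bta-miR-34c (AGGCAGTGTAGTTAGCTGATTG) rose from 83.5 ± 42.7 to 23044.7 ± 23521.0 CPM (8.11 ± 1.02, 0.000364), and that of bta-miR-449a (TGGCAGTGTATTGTTAGCTGGT) from 1.05 ± 0.438 to 756.8 ± 695.6 CPM (9.45 ± 0.9, 0.000157). The smallest p belonged to bta-miR-146b (TGAGAACTGAATTCCATAGGCTGT), which rose from 155.3 ± 9.05 to 19368.1 ± 3930.9 CPM (6.96 ± 0.21, 1.23e-08). The list associated with spermatogonia (miR-221, miR-222, miR-21, miR-146 and others) rose in 20 of 29 cases and none fell (1.22, adjusted p = 0.00139, and adjusted p = 0.202 with an estimated correlation), among them bta-miR-146a (1.82 ± 0.35, 0.00226) and bta-miR-100 (AACCCGTAGATCCGAACTTGTG, 1.79 ± 0.19, 0.000214). In the imprinted DLK1-DIO3 locus, 54 of 70 miRNAs fell and 1 rose, or 56 and 1 adjusted over the list alone (-1.29, adjusted p = 4.1e-16, and adjusted p = 0.524 with an estimated correlation), with bta-miR-487a at -1.87 ± 0.23 (0.000329) and miR-665-x at -3.41 ± 0.39 (0.000259).

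The other miRNA lists did not pass. The let-7 family had 4 of 12 lower, or 2 adjusted over the list alone (median -0.34, adjusted p = 0.0842), including bta-let-7d (-0.75 ± 0.19, 0.00961). miR-17-92 and paralogous clusters had 6 of 24 higher and 7 lower (median 0.26, mean 0.23, tested direction down, adjusted p = 0.732), with bta-miR-19a at -1.12 ± 0.16 (0.000598) and bta-miR-92b (TATTGCACTCGTCCCGGCCTCC) at -2.42 ± 0.19 (4.47e-05). The only measured member of the miR-371 and miR-302 family, miR-371-x, rose (2.9 ± 0.34, 0.000259) and was too few to test as a list. Of 11 X-linked miR-506 family members, 6 rose, or 6 with 1 lower adjusted over the list alone (2.24, adjusted p = 0.172), including bta-miR-507b (3.79 ± 0.49, 0.000382). The Sertoli-associated list (miR-202, miR-132, miR-212 and others) had 7 of 16 higher and 5 lower, or 7 and 6 adjusted over the list alone (median -0.05, mean 0.17, tested direction down, adjusted p = 0.848), with bta-miR-132 rising by 1.49 ± 0.23 (0.000934) and bta-miR-455-5p falling (-1.87 ± 0.25, 0.000418). Smooth muscle miR-143 and miR-145 had 3 of 7 higher (0.58, adjusted p = 0.277), with bta-miR-145 at 0.84 ± 0.2 (0.00598). The endothelial list (miR-126 and miR-139) had 1 of 8 entries higher (0.42, adjusted p = 0.521), bta-miR-139 (0.83 ± 0.19, 0.00568). Haematopoietic miRNAs had 2 of 9 higher (0.14, adjusted p = 0.314), and erythroid miRNAs had 3 of 6 lower, or 4 adjusted over the list alone (-1.18, adjusted p = 0.0911), a list that passed without Y6M replicate 3 (0.0221). Striated muscle miRNAs had 4 of 6 higher and 1 lower (2.41, adjusted p = 0.255), with bta-miR-133a at 3.01 ± 0.42 (0.000522). The germ cell-associated list had 13 of 28 higher and 3 lower (0.44, adjusted p = 0.15), with bta-miR-375 (TTTTGTTCGTTCGGCTCGCGTGA) at 6.9 ± 0.78 (0.000259). The abundant bta-miR-148a (TCAGTGCACTACAGAACTTTGT) fell from 49915.2 ± 4062.1 to 19110.9 ± 2602.9 CPM (-1.39 ± 0.13, 0.000161). In all, 457 miRNAs passed, 51.9% of those tested, with 255 higher and the rest lower, and groups did not overlap for 58% against the 10% of chance.

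**Figure D4:**
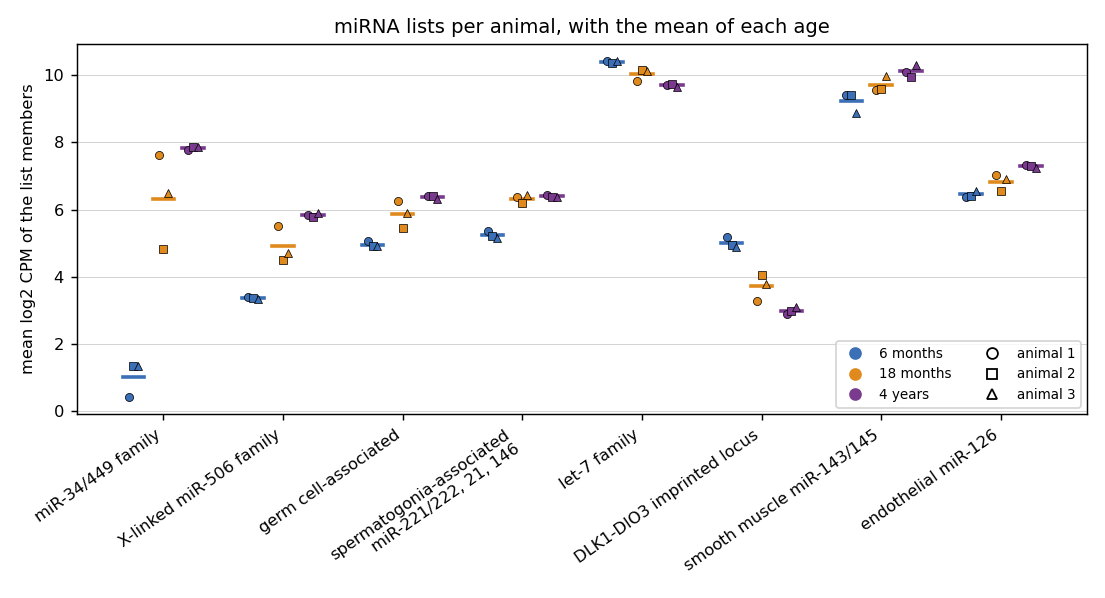
Mean log2 CPM of the members of 8 miRNA lists per library on the y axis, by age. Colours give the age, marker shapes the animal and bars the age mean, and the miR-34 and miR-449 list lies at 7.64, 4.83 and 6.5 in the 18-month libraries against 1.03 ± 0.54 at 6 months.

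Among circRNAs at 18 months against 6 months, novel_circ_011419 from RAD21L1, a meiotic cohesin gene (chromosome 13, minus strand, 59891703 to 59906500, exon and intron), rose from 71.0 ± 12.7 to 1939.4 ± 1077.1 CPM (4.75 ± 0.59, 0.0149). The circRNA novel_circ_048526 from BOLL, a germ cell RNA-binding protein gene (chromosome 2, minus strand, 86270848 to 86290747, annotated exons), rose by 5.41 ± 0.74 (0.0149). That of CIT, novel_circ_020460 (chromosome 17, plus strand, 55575862 to 55605222, annotated exons), was at least 119.1-fold higher (0.0149). The intergenic novel_circ_072521 (chromosome X, plus strand, 24310534 to 24312231) fell from 3372.2 ± 566.9 to 32.5 ± 28.2 CPM (-6.65 ± 0.9, 0.0149), and novel_circ_055642 from AASS, a lysine degradation gene (chromosome 4, minus strand, 86568132 to 86586880, annotated exons), fell from 9744.0 ± 1873.7 to 1933.5 ± 103.5 CPM (-2.33 ± 0.33, 0.0149). Of 3877 circRNAs tested, 5.26% passed, 89.7% of them higher and 21 lower, and groups did not overlap for 32.1% against the 10% of chance. The count was 0 without Y6M replicate 1 (the 5 named circRNAs then had 0.0515), 66 without Y6M replicate 2, 32 without Y6M replicate 3, 45 without Y18M replicate 1, 489 without Y18M replicate 2 and 25 without Y18M replicate 3. It was 0 with replicate number as a block (the 5 named circRNAs then had 0.094 to 0.0971) and 0 in a fit of the 6 libraries alone, where 898 had an unadjusted p under 0.05 in edgeR with all 9, and 315 by DESeq2. The circRNA novel_circ_055642 also missed the threshold without Y6M replicate 3 (0.0524) or Y18M replicate 3 (0.0571).

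The comparison of 4 years with 6 months asked which transcripts differed between the youngest and oldest testes. Haploid germ cell transcripts were higher at 4 years, and the matrix, imprinted and T cell lists were lower, though no list passed with an estimated correlation. PRM1 rose by 10.5 ± 1.23 to 448.8 ± 61.7 CPM (adjusted p = 0.000126) and TNP1 by 10.77 ± 1.41 to 937.1 ± 148.4 CPM (0.0002). The interstitial IGFBP7 (ENSBTAG00000019368) fell from 2359.4 ± 322.6 to 98.1 ± 3.85 CPM (-4.59 ± 0.55, 0.000139), and the matrix glycoprotein SPARC (ENSBTAG00000014835) fell by 5.09 ± 0.41 (3.87e-05). IGF2 fell to 80.7 ± 11.7 CPM (-3.48 ± 0.49, 0.000274), and AMH to 5.51 ± 1.85 CPM (-7.32 ± 0.79, 9.3e-05).

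All 35 acrosome and round spermatid genes rose (median 8.96, adjusted p = 3.16e-11, or 0.503 with an estimated correlation), among them ACRV1 (11.18 ± 1.26, 0.000109), ACR (10.44 ± 0.84, 3.84e-05) and SPATA16 (9.36 ± 0.81, 4.36e-05). All 15 sperm chromatin condensation genes rose (9.91, or 7.81 with genes at 0 set to their bound, adjusted p = 1.94e-06, or 0.503 with an estimated correlation), with CAMK4 at 3.96 ± 0.37 (5.74e-05) and the histone variant H3-5 (ENSBTAG00000017016) at 6.47 ± 0.51 (3.8e-05). Flagellum genes rose in 50 of 51 cases and 1 fell (7.36, adjusted p = 2.56e-14, or 0.503 with an estimated correlation). AKAP4 rose to 272.1 ± 26.7 CPM (7.51 ± 1.03, 0.000245), and DNAH17 (9.49 ± 0.64, 3.24e-05) and SEPTIN12 (9.97 ± 0.67, 3.24e-05) rose as well. All 20 germ cell isoenzymes rose (5.55, adjusted p = 4.26e-07, or 0.503 with an estimated correlation), including LDHC (7.1 ± 0.58, 3.93e-05) and COX6B2 (6.07 ± 0.48, 3.75e-05).

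Meiotic prophase genes rose in 36 of 40 cases, or 37 adjusted over the list alone, and 1 fell (median 4.35, adjusted p = 3.16e-11, and adjusted p = 0.503 with an estimated correlation), with SYCP3 at 4.6 ± 0.38 (4e-05), STAG3 at 6.79 ± 0.47 (3.24e-05) and MEIOC at 8.22 ± 0.5 (3.08e-05). piRNA pathway genes rose in 22 of 25 cases (4.48, adjusted p = 3.71e-08, or 0.503 with an estimated correlation), including PIWIL1 (8.56 ± 0.58, 3.24e-05), TDRD5 (7.15 ± 0.52, 3.53e-05) and DDX4 (5.16 ± 0.41, 3.8e-05). Differentiating spermatogonia genes rose in 10 of 12 cases, or 11 adjusted over the list alone, and 1 fell (2.49, adjusted p = 0.0023, or 0.503 with an estimated correlation). Examples were STRA8 (2.58 ± 0.51, 0.00163), DMRTB1 (5.55 ± 0.43, 3.75e-05) and the DNA methyltransferase DNMT3B (ENSBTAG00000003901, 2.01 ± 0.25, 0.000163). Undifferentiated spermatogonia genes again went both ways, 3 of 15 rising and 5 falling (-1.06, adjusted p = 0.269). NANOS3 rose (3.06 ± 0.36, 0.000125), TSPAN33 (ENSBTAG00000007253) fell (-2.9 ± 0.46, 0.000534) and UCHL1 did not pass (-0.51 ± 0.41, 0.276). Mitotic cell cycle genes rose in 29 of 38 cases and 1 fell (1.95, adjusted p = 1.8e-06, and adjusted p = 0.503 with an estimated correlation), with CDC20 (4.49 ± 0.43, 6.09e-05) and the condensin subunit NCAPH (ENSBTAG00000012925, 3.26 ± 0.32, 6.64e-05).

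Sertoli cell genes fell in 18 of 30 cases, or 19 adjusted over the list alone, and rose in 4 (median -1.82, adjusted p = 0.0121, and adjusted p = 0.618 with an estimated correlation). INHA fell to 107.9 ± 3.36 CPM (-5.25 ± 0.6, 0.000116), INHBA by 3.9 ± 0.37 (6.19e-05) and SOX9 by 1.39 ± 0.26 (0.00134), whereas FATE1 rose by 3.36 ± 0.36 (9.15e-05). Barrier junction genes rose in 6 of 22 cases and fell in 11 (-0.66, adjusted p = 0.372). CLDN11 rose to 202.4 ± 21.8 CPM (4.56 ± 0.64, 0.00027), ESPN by 5.33 ± 0.3 (2.68e-05), and the catenin CTNNB1 (ENSBTAG00000016420) fell by 1.12 ± 0.16 (0.00028). Leydig cell steroidogenesis genes rose in 5 of 20 cases and fell in 11 (-1.42, adjusted p = 0.0876). CYP11A1 (-5.27 ± 0.31, 3e-05), HSD3B1 (-3.23 ± 0.47, 0.000339) and INSL3 (-1.77 ± 0.4, 0.00356) fell, as did, with uncertain identity, STAR (-4.92 ± 0.46, 5.38e-05) and CYP17A1 (-4.27 ± 0.39, 5.15e-05). CYP19A1 (8.06 ± 0.57, 3.3e-05) and HSD17B3 (ENSBTAG00000016867, 3.26 ± 0.26, 3.87e-05), which makes testosterone, rose. Cholesterol biosynthesis genes fell in 18 of 24 cases and 1 rose (-2.35, adjusted p = 6.74e-05, and adjusted p = 0.503 with an estimated correlation), with MSMO1 at -3.06 ± 0.23 (3.53e-05) and NSDHL (ENSBTAG00000009231) at -3.55 ± 0.24 (3.24e-05).

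Extracellular matrix genes fell in 34 of 36 cases and 2 rose (median -3.11, adjusted p = 3.37e-08, and adjusted p = 0.503 with an estimated correlation), with COL1A1 at -4.77 ± 0.73 (0.000442) and the basement membrane collagen COL4A2 (ENSBTAG00000025210) at -5.76 ± 0.44 (3.75e-05). Interstitial progenitor and fibroblast genes fell in 19 of 23 cases and none rose (-2.49, adjusted p = 1.48e-05, and adjusted p = 0.503 with an estimated correlation), with TCF21 (-4.74 ± 0.47, 6.91e-05) beside IGFBP7. Peritubular myoid and smooth muscle genes rose in 3 of 17 cases and fell in 9 (-1.19, adjusted p = 0.175). CALD1 (-2.71 ± 0.36, 0.000211) and the intermediate filament DES (ENSBTAG00000005353, -2.99 ± 0.53, 0.000917) fell, and ACTA2 did not pass (0.59 ± 0.55, 0.35). Endothelium genes fell in 17 of 23 cases and rose in 4 (-1.69, adjusted p = 0.00364, and adjusted p = 0.503 with an estimated correlation), PECAM1 by -1.38 ± 0.26 (0.00135) and KDR by -1.8 ± 0.17 (5.58e-05), while VWF rose by 2.96 ± 0.34 (0.00012).

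T cell and pan-leukocyte genes fell in 18 of 22 cases, or 19 adjusted over the list alone, and none rose (median -2.81, adjusted p = 0.00111, and adjusted p = 0.606 with an estimated correlation). LCK (ENSBTAG00000012695), a T cell kinase, fell by 3.16 ± 0.59 (0.00117) and CD3E (ENSBTAG00000015710), of the T cell receptor complex, by 2.99 ± 0.65 (0.00273). Macrophage genes fell in 14 of 21 cases and rose in 3 (-1.94, adjusted p = 0.0769), and the list passed without Y6M replicate 3 (0.04). The mannose receptor MRC1 (ENSBTAG00000038048) rose from 26.3 ± 2.01 to 142.5 ± 17.7 CPM (2.44 ± 0.29, 0.000128), AIF1 (ENSBTAG00000020554) rose (3.14 ± 0.59, 0.00122) and ITGAM fell (-3.32 ± 0.46, 0.000249). Of 7 erythrocyte genes, 2 rose and 1 fell (0.34, adjusted p = 0.873), HEMGN being 2391.4-fold higher against 3 counts (counting interval 818 to 11598.2, 0.000206). Rete testis, efferent duct and epididymis genes rose in 1 of 8 cases and fell in 4 (-2.53, adjusted p = 0.199), with EPCAM at 5.02 ± 0.47 (5.65e-05) and ESR1 at -3.68 ± 0.43 (0.000126).

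Imprinted growth genes fell in 18 of 24 cases and rose in 4 (median -2.53, adjusted p = 0.00171, and adjusted p = 0.503 with an estimated correlation), among them SGCE (-2.46 ± 0.23, 5.69e-05) and CDKN1C (-4.46 ± 0.23, 2.18e-05). Hypoxia response genes rose in 7 of 29 cases and fell in 15 (-1.23, adjusted p = 0.175), with CA9 at 8.11 ± 0.65 (3.81e-05) and the angiogenic factor VEGFA (ENSBTAG00000005339) at -2.78 ± 0.29 (7.79e-05). Oxidative phosphorylation genes rose in 9 of 35 cases and fell in 15 (-0.31, adjusted p = 0.234), including SDHD (-1.52 ± 0.17, 0.000108). Among the smallest p values over all genes, DEFB119 was 5502.3-fold higher against 2 counts (counting interval 1522.9 to 45438.3, 9.12e-06). PRSS45 (8.91 ± 0.41, 1.89e-05), PKMYT1 (6.3 ± 0.32, 2.18e-05) and the centriolar CEP83 (ENSBTAG00000004484, 4.72 ± 0.25, 2.21e-05) rose, as did SLC6A9, of uncertain identity (9.28 ± 0.38, 9.12e-06). CCL25 (-8.52 ± 0.35, 9.12e-06), RHBDL2 (-5.07 ± 0.25, 2.18e-05), KLK1 (-5.42 ± 0.3, 2.68e-05) and, of uncertain identity, GPC6 (-6.0 ± 0.28, 1.89e-05) fell. In all, 12372 of 16742 genes passed, 6152 higher and 6220 lower, and groups did not overlap for 83.1% against the 10% of chance. Called genes were higher in 49.7% of cases, 53.6% with DESeq2, 58.3% with library size alone and 46.1% with upper-quartile factors, which shifted the median log2 fold change by 0.18, 0.29 and -0.19.

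Among miRNAs at 4 years against 6 months, all 5 of the miR-34 and miR-449 family rose (median 7.89, adjusted p = 0.00498, and adjusted p = 0.524 with an estimated correlation). Of these, bta-miR-34c reached 47095.9 ± 6271.5 CPM (9.14 ± 1.07, 8.54e-05) and bta-miR-449a 1514.4 ± 81.7 CPM (10.45 ± 0.93, 3.48e-05). DLK1-DIO3 miRNAs fell in 61 of 70 cases and none rose (-2.03, adjusted p = 1.01e-18, and adjusted p = 0.504 with an estimated correlation), including bta-miR-410 (AATATAACACAGATGGCCTGT, -2.68 ± 0.24, 3.48e-05) and miR-665-x (AGGGGTCTTGGCCTCTGCCC), from 44.3 ± 19.4 to 0.178 ± 0.103 CPM (-7.89 ± 0.54, 1.09e-05). The let-7 family fell in 9 of 12 cases (-0.61, adjusted p = 0.0176, and adjusted p = 0.529 with an estimated correlation), with bta-let-7f (TGAGGTAGTAGATTGTATAGTT) falling from 101466.6 ± 9667.8 to 29884.2 ± 3210.0 CPM (-1.76 ± 0.26, 0.000301). The X-linked miR-506 family rose in 7 of 11 cases (3.34, adjusted p = 0.0449, and adjusted p = 0.524 with an estimated correlation), with bta-miR-507b at 4.75 ± 0.51 (6.86e-05). That list's call was lost without Y6M replicate 1 (0.0518), 2 (0.0611) or 3 (0.0628), without Y4Y replicate 2 (0.055) or 3 (0.0743), and with library size alone (0.057). Spermatogonia-associated miRNAs rose in 19 of 29 cases and 1 fell (1.43, adjusted p = 0.0165, and adjusted p = 0.321 with an estimated correlation), with bta-miR-146a at 2.11 ± 0.35 (0.000583) and bta-miR-100 at 2.2 ± 0.19 (3.48e-05).

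The remaining miRNA lists did not pass at 4 years against 6 months. miR-17-92 and paralogous clusters had 14 of 24 higher and 7 lower (median 0.86, adjusted p = 0.628), with bta-miR-92a (TATTGCACTTGTCCCGGCCTGT) falling from 9170.9 ± 902.9 to 2185.7 ± 79.9 CPM (-2.07 ± 0.19, 3.48e-05). miR-371-x rose by 2.99 ± 0.33 (7.52e-05). The Sertoli-associated list had 5 of 16 higher and 6 lower, or 6 and 6 adjusted over the list alone (-0.28, adjusted p = 0.581), with miR-202-y at -2.61 ± 0.31 (8.56e-05). Smooth muscle miR-143 and miR-145 had 5 of 7 higher (0.94, adjusted p = 0.0842), and bta-miR-143 (TGAGATGAAGCACTGTAGCTCG) rose from 65689.4 ± 16262.6 to 144648.4 ± 12879.0 CPM (1.14 ± 0.19, 0.000511). The endothelial list had 6 of 8 entries higher (0.92, adjusted p = 0.0842), with miR-126-y at 0.85 ± 0.21 (0.00641). Haematopoietic miRNAs had 2 of 9 higher and 3 lower, or 2 and 0 adjusted over the list alone (median -0.76, mean 0.51, tested direction up, adjusted p = 0.802). None of 6 erythroid miRNAs passed (-0.76, adjusted p = 0.251), and striated muscle miRNAs had 4 of 6 higher and 2 lower (2.35, adjusted p = 0.388), with bta-miR-133a at 2.57 ± 0.42 (0.000497). The germ cell-associated list had 19 of 28 higher and 5 lower (0.7, adjusted p = 0.0812), with bta-miR-375 reaching 1272.8 ± 99.6 CPM (8.01 ± 0.82, 5.64e-05). The smallest p values belonged to bta-miR-146b, at 20864.8 ± 1291.5 CPM (7.07 ± 0.21, 1.11e-08), and a miRNA outside the files' known and existing classes (TGAGCACACCTGCCTGAGCAGA, 7.46 ± 0.3, 1.35e-07). bta-miR-153 (3.36 ± 0.28, 3.06e-05) also rose, and bta-miR-92b (-2.57 ± 0.19, 1.91e-05) and bta-miR-503-3p (-3.81 ± 0.34, 3.48e-05) fell. In all, 577 miRNAs passed, 65.5% of those tested, with 316 higher and 261 lower, with groups not overlapping for 73.8% against the 10% of chance. Library size alone shifted the median log2 fold change by 0.19.

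Among circRNAs at 4 years against 6 months, novel_circ_032419 from EAPP (chromosome 21, minus strand, 44945325 to 44948098, annotated exons) was at least 2025.3-fold higher, at 18109.6 ± 2804.5 CPM (adjusted p = 0.00556). The RAD21L1 circRNA novel_circ_011419 rose to 3830.7 ± 698.5 CPM (5.73 ± 0.62, 0.00556), and that of FAM227B, novel_circ_002280 (chromosome 10, plus strand, 60723815 to 60763633, exon and intron), rose by 5.62 ± 0.72 (0.00556). The RAVER2 circRNA novel_circ_052192 (chromosome 3, minus strand, 80632625 to 80662543, annotated exons) fell by 5.58 ± 0.63 (0.00556). The SOBP circRNA novel_circ_069840 (chromosome 9, minus strand, 42527387 to 42557580, annotated exons) was at least 33.9-fold lower (0.00617). The intergenic novel_circ_068472 (chromosome 8, minus strand, 91265345 to 91276385) fell from 4734.6 ± 761.0 to 503.2 ± 93.8 CPM (-3.23 ± 0.49, 0.00658). In all, 815 of 3877 circRNAs passed, 590 higher and 225 lower, with groups not overlapping for 49.5% against the 10% of chance. The count was 325, 481 and 343 without Y6M replicates 1, 2 and 3, between 407 and 420 without any 1 of Y4Y replicates 1, 2 and 3, and 129 with replicate number as a block. With the library size factors of the gene table, chosen after seeing the data, 876 passed, 438 higher and 438 lower, so the higher share was 50% against 72.4%, and the median was -0.53 against 0.16. Library size alone and upper-quartile factors shifted the median by -0.23 and -0.2.

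**Figure D5:**
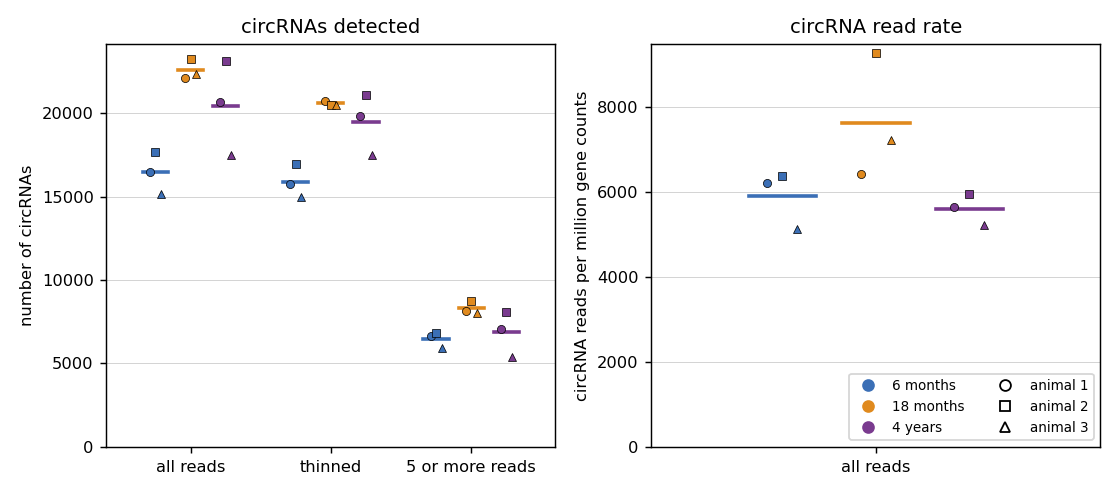
Number of circRNAs detected per library in the left panel, from all reads, after thinning to equal reads and with at least 5 reads. The right panel gives circRNA reads per M gene counts. Colours give the age, marker shapes the animal and bars the age mean. With all reads the means lie at 16448.3, 22578 and 20437.3 at 6 months, 18 months and 4 years.

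The comparison of 4 years with 18 months asked what differed between the older ages. Here 14 gene lists passed without any member passing, but regrouping the 6 libraries gave up to 17, so these calls stay undecided. T cell and pan-leukocyte genes were lower (median -1.89, adjusted p = 1.16e-06, or 0.503 with an estimated correlation), with 14 of 22 lower adjusted over the list alone, and a mean log2 CPM of 2.49 ± 1.1 at 18 months and 0.97 ± 0.22 at 4 years (difference -1.51, or -0.95 without Y18M replicate 2). Flagellum genes were higher (0.8, adjusted p = 6.52e-09, or 0.503 with an estimated correlation), by a mean of 1.17, or 0.48 without Y18M replicate 2 and 1.69 without Y18M replicate 1.

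Across the germ cell lists, the acrosome and round spermatid list (median 1.05, adjusted p = 3.37e-08), the sperm chromatin list (0.89, 0.000155) and the isoenzyme list (0.75, 5.35e-05) were higher (each adjusted p = 0.503 with an estimated correlation). Without Y18M replicate 2 their differences in mean log2 CPM fell from 1.58, 1.42 and 1.09 to 0.64, 0.62 and 0.45. The meiotic prophase list (0.39, 0.0105) and the piRNA list (0.32, 0.019) were higher and the undifferentiated spermatogonia list was lower (-0.58, 0.0458), each with an adjusted p = 0.65 with an estimated correlation. Without Y18M replicate 2 those last 3 calls were lost (0.228, 0.256 and 0.78), and the undifferentiated call was also lost without Y18M replicate 3 (0.064) or Y4Y replicate 1 (0.0684) or 2 (0.0603), and with library size alone (0.0604). Differentiating spermatogonia (median 0, mean -0.1, tested direction up, adjusted p = 0.941) and mitotic cell cycle genes (0.16, 0.196) did not pass. Without passing, PRM1 was at 1.76 ± 0.81 (0.244), TNP1 at 1.26 ± 0.92 (0.4), ACRV1 at 1.09 ± 0.74 (0.375), AKAP4 at 1.82 ± 0.78 (0.225) and LDHC at 0.5 ± 0.45 (0.484). Others were the kinase TSSK6 (ENSBTAG00000006649, 1.78 ± 0.84, 0.251), the chromatin remodeller CHD5 (ENSBTAG00000040477, 1.38 ± 0.51, 0.192), the fibrous sheath protein CABYR (ENSBTAG00000005638, 0.98 ± 0.42, 0.225) and the hexokinase HK1 (ENSBTAG00000012380, 0.96 ± 0.34, 0.182). DDX4 had 0.68 ± 0.34 (0.272), STRA8 0.46 ± 0.47 (0.537), SYCP3 -0.04 ± 0.32 (0.94) and UCHL1 -1.13 ± 0.41 (0.187). Without Y18M replicate 1, PRM1 (3.04, 0.017), ACRV1 (2.19, 0.0334), AKAP4 (2.92, 0.0207), DDX4 (1.06, 0.0308), UCHL1 (-1.44, 0.0157), TSSK6 (2.92, 0.0257), CHD5 (2.28, 0.00619), CABYR (1.47, 0.0225) and HK1 (1.48, 0.00619) passed.

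Sertoli cell genes were lower as a list (median -0.7, adjusted p = 0.000883, or 0.503 with an estimated correlation), with 5 of 30 lower adjusted over the list alone. So were extracellular matrix genes (-0.93, 1.51e-06, 10 of 36 lower adjusted over the list alone) and interstitial progenitor genes (-0.92, 0.000206, 6 of 23 lower adjusted over the list alone), each with adjusted p = 0.503 with an estimated correlation. Without Y18M replicate 2 these 3 differences in mean log2 CPM shrank from -0.63, -0.83 and -0.79 to -0.32, -0.39 and -0.41. The myoid list (-0.7, 0.0135) and the imprinted list (-0.65, 0.0129) were lower, each with adjusted p = 0.606 with an estimated correlation. Both calls were lost without Y18M replicate 2 (0.247 and 0.125). Oxidative phosphorylation genes were lower (-0.21, adjusted p = 0.0437, or 0.503 with an estimated correlation), a call lost without Y18M replicate 1 (0.172) or 3 (0.139), without Y4Y replicate 1 (0.0639) or 3 (0.0925), and with replicate number as a block (0.0714). No call was made for barrier junction (-0.23, 0.676), Leydig (median -0.05, mean 0.04, tested direction up, 0.704, with 2 higher and 3 lower adjusted over the list alone) or cholesterol genes (median 0.15, mean -0.01, tested direction up, 0.811). Nor was one made for endothelium (-0.12, 0.404), macrophage (-0.79, 0.326, with 3 higher and 5 lower adjusted over the list alone), erythrocyte (-0.33, 0.941), rete testis (-1.18, or -1.11 at the bound, 0.404) or hypoxia genes (median 0.07, mean -0.11, tested direction up, 0.613).

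Of the somatic anchors, none passed. AMH was at -3.24 ± 0.66, INHA at -1.76 ± 0.52, CYP17A1, of uncertain identity, at -1.12 ± 0.35, COL1A1 at -2.13 ± 0.66 and IGF2 at -1.73 ± 0.45 (each adjusted p = 0.174). SOX9 was at -0.62 ± 0.26 (0.22), ACTA2 at -1.53 ± 0.56 (0.188), CLDN11 at -0.51 ± 0.55 (0.553), INSL3 at -0.23 ± 0.39 (0.707), HSD3B1 at -0.34 ± 0.44 (0.625), STAR, of uncertain identity, at -0.04 ± 0.39 (0.959) and PECAM1 at 0.02 ± 0.26 (0.964). The laminin LAMA1 (ENSBTAG00000018160, -1.98 ± 0.42), the intermediate filament NES (ENSBTAG00000015794, -1.89 ± 0.36), LCK (-2.3 ± 0.57), the Sertoli cell morphogen DHH (ENSBTAG00000000124, -1.12 ± 0.33) and MRC1 (1.53 ± 0.28) had the same adjusted p of 0.174. Without Y18M replicate 1, AMH (-3.7, 0.00612), INHA (-2.17, 0.00666), CYP17A1 (-1.36, 0.0132), COL1A1 (-2.53, 0.0148), IGF2 (-2.09, 0.00656), SOX9 (-0.85, 0.017), ACTA2 (-1.95, 0.0128), LAMA1 (-2.34, 0.00612), NES (-2.22, 0.00612), LCK (-2.68, 0.00766), DHH (-1.31, 0.0192) and MRC1 (1.77, 0.0067) passed. DESeq2 called AMH (-3.12, 7.79e-05), INHA (-1.65, 0.03), COL1A1 (-2.02, 0.0377), IGF2 (-1.62, 0.0164), LAMA1 (-1.88, 0.00151), NES (-1.79, 0.000536), LCK (-2.19, 0.00695) and MRC1 (1.59, 0.00063). In edgeR, 1 of 16742 genes passed, 3572 had an unadjusted p under 0.05, and groups did not overlap for 25.4% against the 10% of chance. The last share was not tested and can lie far from 10% by chance. DESeq2 called 876, 187 higher and 689 lower. The edgeR count was 5607 without Y18M replicate 1 (2247 higher, 3360 lower), 2 without Y18M replicate 2, and 0 without any 1 of the Y4Y replicates. Library size alone and upper-quartile factors shifted the median log2 fold change by -0.11 and -0.12.

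Among miRNAs at 4 years against 18 months, a miRNA outside the files' known and existing classes (GTGGGACGCGTGCGTTTT) fell from 147.8 ± 37.3 to 25.8 ± 5.16 CPM (-2.52 ± 0.26, 0.00184) and miR-452-x (AACTGTTTGCAGAGGAAACTGA) from 162.1 ± 70.3 to 31.7 ± 1.87 CPM (-2.36 ± 0.31, 0.00428). bta-miR-31 (AGGCAAGATGCTGGCATAGCT) fell from 727.2 ± 324.8 to 175.7 ± 10.3 CPM (-2.05 ± 0.29, 0.00673), miR-224-y by 1.76 ± 0.26 (0.00673) and miR-665-x by 4.48 ± 0.58 (0.00428). bta-miR-4286 (ACCCCACTCCTGGTACC) rose from 5.28 ± 0.11 to 16.8 ± 2.34 CPM (1.67 ± 0.22, 0.00428). DLK1-DIO3 miRNAs fell in 18 of 70 cases, or 28 adjusted over the list alone, and none rose (median -0.85, adjusted p = 7.21e-13, and adjusted p = 0.524 with an estimated correlation). One of them, bta-miR-410 (-1.24 ± 0.24, 0.0167), missed the threshold without Y4Y replicate 2 (0.0544) and with replicate number as a block (0.0573).

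Other miRNA lists that passed had few or no members passing. The X-linked miR-506 family was higher (median 0.79, 0 of 11 called, adjusted p = 0.00451, or 0.504 with an estimated correlation). The miR-34 and miR-449 family was higher (1.03, 0 of 5 called, adjusted p = 0.0225, and adjusted p = 0.553 with an estimated correlation), and so was endothelial miR-126 (0.44, 1 of 8 higher, or 4 adjusted over the list alone, adjusted p = 0.0238, and adjusted p = 0.529 with an estimated correlation). Both calls were lost without Y18M replicate 2 (0.0588 and 0.0711). The let-7 family was lower (-0.36, 1 of 12 called, adjusted p = 0.0238, or 0.553 with an estimated correlation), a call lost without Y4Y replicate 3 (0.0541) and with library size alone (0.0561). The lists that did not pass were miR-17-92 (0.27, 1 of 24 lower, 0.0842), germ cell-associated (0.27, 1 higher and 2 lower of 28, or 2 and 2 adjusted over the list alone, 0.0842), miR-143 and miR-145 (0.41, 0 of 7, 0.0989) and Sertoli-associated (-0.22, 3 of 16 lower, or 1 higher and 5 lower adjusted over the list alone, 0.212). Without Y18M replicate 1 the germ cell-associated (0.038) and miR-17-92 lists (0.049) passed, as did miR-143 and miR-145 without Y18M replicate 3 (0.0495). Haematopoietic (-0.69, 0 of 9, 0.349), erythroid (0.35, 0 of 6, 0.581), striated muscle (-0.08, 0 of 6, 0.723) and spermatogonia-associated miRNAs (median 0.09, mean -0.01, tested direction up, 2 of 29 lower, 0.758) did not pass, and miR-371-x was at 0.1. In all, 84 miRNAs passed, 9.53% of those tested, with 9 higher and 75 lower, and the median over all tested was 0.04. Groups did not overlap for 34.2% against the 10% of chance. DESeq2 called 36 higher and 97 lower (27.1% higher against 10.7%). The count was 286 (43.7% higher), 33 and 27 without Y18M replicates 1, 2 and 3. It was 33, 12 and 34 without Y4Y replicates 1, 2 and 3, 20 with a replicate block, and 12 with the 6 libraries alone. Library size alone shifted the median by 0.11.

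No circRNA passed at 4 years against 18 months in edgeR, where the lowest adjusted p was 0.172 and 298 of 3877 had an unadjusted p under 0.05. DESeq2 called 1, edgeR with no filter on low counts called 29, and 1 passed without Y18M replicate 1. Groups did not overlap for 19.2% against the 10% of chance. Library size alone and upper-quartile factors shifted the median by -0.17 and -0.15.

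A further question was whether genes on the X chromosome, which is silenced during meiosis in mammals, moved apart from autosomal genes. At 18 months against 6 months, 152 of 293 X-linked genes fell and 44 rose, with a median of -0.88 against 0.08 for 9172 autosomal genes. At 4 years against 6 months, 193 fell and 43 rose (-1.32 against 0.07). None of the 293 passed at 4 years against 18 months (-0.52 against 0.04). The difference of medians was -0.96, -1.39 and -0.56 in the 3 comparisons (camera p = 1.2e-06, 2.4e-08 and 5.2e-09, and p = 0.366, 0.304 and 0.284 with an estimated correlation). Without Y18M replicate 2, the difference at 4 years against 18 months was -0.19. Only genes that host a circRNA were placed on a chromosome.

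Another question was whether circRNAs moved with their host genes. Over 3626 circRNAs of 2123 hosts, Pearson's r between log2 fold changes was 0.63 at 18 months against 6 months, 0.66 at 4 years against 6 months and 0.39 at 4 years against 18 months, with Spearman's rho of 0.56, 0.6 and 0.43. These are correlations across circRNAs, which are not independent replicates. Leaving out 1 library gave r of 0.53 to 0.6, 0.6 to 0.63 and 0.25 to 0.44. The circRNA and host moved in opposite directions in 32.8%, 29.6% and 35.7% of pairs. Where both passed, they were opposite in 6 pairs at 18 months and in 49 of 617 at 4 years against 6 months. The number of circRNAs detected was 16448.3 ± 1264.7 at 6 months, 22578 ± 593.6 at 18 months and 20437.3 ± 2825.8 at 4 years (exact permutation p = 0.025, adjusted p = 0.0491, family of 11). After thinning to equal reads it was 15897, 20577.3 and 19479.7 (exact permutation p = 0.0143, adjusted p = 0.0393). With at least 5 reads it was 6468.3 ± 473.3, 8299.3 ± 387 and 6859.7 ± 1352.9, which did not pass (exact permutation p = 0.132, adjusted p = 0.161). The circRNA reads per M gene counts were 5903.1 ± 680, 7626 ± 1475.2 and 5600.7 ± 362.6 (exact permutation p = 0.0357, adjusted p = 0.0491), the highest being 9265.2 in Y18M replicate 2.

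The authors' tables of differing genes listed 7668 for 18 months against 6 months. They listed 10565 for 4 years against 6 months and 247 for 4 years against 18 months. Of these, 7576, 10346 and 245 were tested here, 7442, 9887 and 1 passed in the same direction, and 6, 24 and 0 passed in the opposite direction. Their miRNA tables listed 462, 676 and 176, of which 80.1%, 70% and 73.9% were tested here. Among all listed, 72.9%, 67.2% and 29.0% passed in the same direction, and 33, 19 and 79 were tested and did not pass. Their circRNA tables, selected on unadjusted p, listed 1841, 3962 and 908, of which 760, 1515 and 247 were tested here. Among all listed, 11.1%, 20.4% and 0% passed in the same direction, and 556, 707 and 247 were tested and did not pass. In those circRNA tables, 63, 811 and 0 had a false discovery rate under 0.05.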

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

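Chosen only after the data were seen were the circRNA counts with the factors of the gene table and every alternative for the miRNA lists. Counts kept within 1.5 times the value given under every alternative run for genes at 18 months against 6 months (8019 to 11953) and 4 years against 6 months (10338 to 13243), and for miRNAs in the same comparisons (22.7% to 32.2% and 30% to 43.2% of the 1536 deposited). X-linked genes stayed below autosomal genes in all 3 comparisons (-1.22 to -0.72, -1.48 to -1.38 and -0.82 to -0.19, the last without Y18M replicate 2). Of 2178 values of named features under DESeq2, library size alone, a replicate block or leaving out 1 library, 97.0% kept direction and call. Another 31 newly passed, 20 no longer passed and 14 changed sign. Anchors aside, these features were picked for small p, so the share can overstate stability.

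DESeq2 gave 876 genes, 8.66% of miRNAs and 1 circRNA at 4 years against 18 months, and 315 circRNAs at 18 months against 6 months. With replicate number as a block, 1.3% of miRNAs passed at 4 years against 18 months, and 0 and 129 circRNAs at 18 months and 4 years against 6 months. The 6 libraries alone gave 0 genes and 0.781% of miRNAs at 4 years against 18 months and 0 circRNAs at 18 months against 6 months, with fewer libraries to estimate the spread. Without a filter on low counts, 29 circRNAs passed at 4 years against 18 months. With an estimated correlation, 0 gene lists passed in any of the 3 comparisons, against 15, 15 and 14, and 0 miRNA lists, against 3, 5 and 5. The second filter kept 8715 circRNAs, against 3877. With it, r between circRNAs and hosts was 0.54 and 0.59 at 18 months and 4 years against 6 months. The ratio of circRNAs detected at 4 years to 6 months was 1.06 with at least 5 reads, against 1.24 with all reads. The exact permutation p over the 3 ages was 0.132 and 0.025. Between 4 years and 6 months alone it was 0.7 and 0.2, so neither ratio passed.

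Leaving out 1 library gave 0 (without any Y4Y replicate) to 5607 genes (without Y18M replicate 1), 9 (without Y18M replicate 2) to 13 gene lists, 0.781% (without Y4Y replicate 2) to 18.6% of miRNAs (without Y18M replicate 1), 3 (without Y18M replicate 2) to 7 miRNA lists (without Y18M replicate 1), and 0 to 1 circRNA (without Y18M replicate 1) at 4 years against 18 months. For circRNAs it gave 0 (without Y6M replicate 1) to 489 (without Y18M replicate 2) at 18 months and 325 (without Y6M replicate 1) to 481 (without Y6M replicate 2) at 4 years against 6 months.

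At 4 years against 18 months, features that did not pass changed sign. Leaving out 1 library gave SYCP3 -0.15 to 0.04, STAR -0.49 to 0.32, INSL3 -0.52 to 0.03, PECAM1 -0.13 to 0.26 and miR-371-x -0.06 to 0.2. DESeq2 gave SYCP3 0.03 and STAR 0.05, and library size alone gave PECAM1 -0.11. At 18 months against 6 months, the hypoxia, macrophage and T cell lists also passed with library size alone (0.0347, 0.0339 and 0.0292), and the first 2 with a replicate block (0.0448 and 0.0459). With the factors of the gene table, 87% of the circRNAs called at 18 months against 6 months were higher, 438 passed higher and 438 lower at 4 years against 6 months, and 0 passed at 4 years against 18 months. Apart from the smaller fits, the cause was not tested. Depth limits the number of circRNAs detected, which at 18 months was 22578 and after thinning 20577.3. What limits calls of circRNAs was not separated into depth and spread. No alternative from the plan was left out.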

Other observations

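The tests chosen only after the result was seen were those of a wrong age label on Y18M replicates 1 and 2, of somatic RNA diluted by germ cell RNA and of TMM scaling, and the circRNAs opposed to their hosts were picked after their values were seen.

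The 10 most abundant genes held 14.2 ± 0.214% of gene counts at 6 months, 7.2 ± 3.34% at 18 months and 4.51 ± 0.193% at 4 years (exact permutation p = 0.0107 over the 3 ages, adjusted p = 0.0392, n = 3 per age). RPS29, a ribosomal protein gene, led at each age with 5.72 ± 0.477%, 3.42 ± 2.04% and 1.58 ± 0.12%. At 6 months the translation factor EEF1A1 (1.88 ± 0.277%), the metalloproteinase inhibitor TIMP2 (1.34 ± 0.304%) and INSL3 (0.965 ± 0.275%) followed. Mitochondrial COX1 stood at 13141.8 CPM in Y18M replicate 2, against 36.6 and 61.2 CPM in the other 18-month libraries. PRM1 and TNP1 together held 7.06e-05 ± 4.47e-05%, 0.0562 ± 0.0567% and 0.144 ± 0.0159% of gene counts (exact permutation p = 0.00357, the smallest that 280 groupings allow, adjusted p = 0.0196). Extracellular matrix genes held 1.62 ± 0.156%, 0.262 ± 0.154% and 0.105 ± 0.000865% (exact permutation p = 0.00357, adjusted p = 0.0171).

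Among miRNAs, bta-let-7f was the most abundant at 6 months (9.5 ± 0.888% of counts) and bta-miR-143 at 18 months (9.84 ± 1.43%) and 4 years (15.5 ± 1.07%), where bta-miR-34c held 5.06 ± 0.761%. The number of miRNAs with a count was 1157.3 ± 14.6, 1260.3 ± 18.1 and 1349.7 ± 26.8 at the 3 ages (exact permutation p = 0.00357, adjusted p = 0.0196). Of the pairs in which a circRNA and its host both passed in opposite directions at 4 years against 6 months, novel_circ_020554 (chromosome 17, 57036592 to 57052038) rose by 7.49 ± 1.18 (0.00981) while its host, the kinase gene TAOK3, fell by 1.33 ± 0.18 (0.00024). In the other direction, novel_circ_061820 (chromosome 6, 67740025 to 67764471) fell by 2.6 ± 0.5 (0.0133) and its host DCUN1D4 rose by 1.29 ± 0.21 (0.000532).

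The 18-month libraries spread between the 6-month and the 4-year libraries, with Y18M replicate 2 nearest to 6 months. A mixture of 6-month-like and 4-year-like RNA in that library would give every germ cell list the same weight on the way from the 6-month to the 4-year mean, but the median weight was 0.5 (quartiles 0.4 and 0.69) for meiotic prophase and 0.13 (0.06 and 0.29) for 97 spermatid genes, a difference of 0.37 that argues against it. A wrong age label on Y18M replicate 2 is argued against by its highest mean correlation with another age, 0.82 with 6 months and 0.8 with 4 years, where the lowest within either age was 0.98. For Y18M replicate 1 a wrong age label and an 18-month testis already like those of 4 years cannot be told apart, since its mean correlation with the 4-year libraries was 0.98, equal to the lowest within that age, and since its position on features that separated the others (0.87 for genes, 0.77 for miRNAs) lay below those of 4-year libraries held out alike (from 0.95, SD 0.03, and from 0.93, SD 0.06) by less than 3 SD. A candidate explanation, as a hypothesis, is that animals of 18 months differed in how far spermatogenesis had advanced, which may also fit weights of 0.87 and 0.54 in Y18M replicate 3, but stage was not scored.

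Somatic cell lists were lower at 4 years than at 6 months, though the Leydig, myoid and macrophage lists did not pass, and none passed with an estimated correlation. If unchanged somatic RNA had only been diluted by germ cell RNA, lists silent in germ cells would have fallen alike. Relative to the endothelium list, which changed by -1.3, the extracellular matrix list changed by -1.85 (SE 0.03) and the interstitial list by -1.17 (SE 0.05). The T cell list changed by -1.03 (SE 0.45) and the other 4 by 0.17 to 0.68. Members of these 4 and of endothelium went both ways, and germ cell expression was not measured, so dilution stays open. TMM scaling is argued against as the cause, since with library size alone the highest of the 8 medians was still -0.91. A lower expression per cell and a lower share of matrix-producing cells with age both stay open, as untested, because counts per cell were not measured.

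X-linked genes were lower than autosomal genes at 4 years against 6 months (camera p = 2.4e-08, and p = 0.304 with an estimated correlation). A difference in expression level between X-linked and autosomal genes is argued against by autosomal genes matched on mean CPM at 6 months, over 1000 draws, with which the difference was -1.36 (SD of the draws 0.13), and -0.93 and -0.55 in the other comparisons (SD 0.08 and 0.04). Silencing of the X chromosome in germ cells and a change in the shares of cell types both stay open, as untested, since cell shares were not measured.

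The 6 libraries of 2 ages can be split in 10 ways, too few for a share under 0.05. For genes, the real split and the highest other gave 10026 and 0 at 18 months against 6 months, 12372 and 0 at 4 years against 6 months, and 1 and 1 at 4 years against 18 months, so 1, 1 and 2 splits gave as many as the real one. For miRNAs they gave 457 and 0, 577 and 0, and 84 and 0 (1, 1 and 1 splits). For circRNAs, 5.26% of those tested passed in the real split and 1 circRNA in the highest other at 18 months, 815 and 0 at 4 years against 6 months, and 0 and 0 at 4 years against 18 months (1, 1 and 10 splits). Gene lists gave 15 and 16, 15 and 16, and 14 and 17 (5, 7 and 6 splits), and miRNA lists 3 and 6, 5 and 7, and 5 and 5 (7, 5 and 2 splits). Every other split mixes the ages 2 to 1, keeping part of their difference and widening the spread within groups, so all counts stay undecided. For X-linked genes the differences were -0.96 and -0.62, -1.39 and -0.52, and -0.56 and -0.62 (1, 1 and 3 splits). Replicate numbers carried no sign of pairing across ages, with correlations between same-numbered libraries after removing the age means of -0.14 to 0.1 for genes, -0.18 to 0.09 for miRNAs and -0.02 to 0.01 for circRNAs (9 pairs each).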
